A study of Mus musculus with 4 samples.

How the data were processed

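Total RNA from mouse hearts collected 1 week after transverse aortic constriction (TAC, a surgical narrowing of the aorta that loads the left ventricle with pressure) was hybridised as biotin-labelled cRNA to 4 Affymetrix Mouse Gene ST arrays, 1 from a wild type heart and 3 from hearts without MAFbx (atrogin-1, encoded by Fbxo32), per the labels. The labels number the hearts within a genotype but do not say outright that each is a separate animal. The p-values therefore rest on a spread between samples, which here comes from the 3 knockout samples alone. The deposited values are on the log2 scale, and the authors made them with Affymetrix Expression Console and RMA (background correction, quantile normalization between arrays and summary per probe set), per the submitters' processing notes. Versions of both are not given in the sources used here. RMA forces the arrays to nearly the same distribution, so a change shared by most genes would be removed, and its background step compresses differences between dim genes. Scanner intensities were not analysed here.

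The table held 35556 probe sets. In the platform annotation 21789 had 1 gene symbol, 1621 had several and 12146 were unlisted, and genes were named only from those with 1 symbol. Of these probe sets 21698 matched a gene of the GRCm38.p6 reference table by gene identifier and 0 symbols were updated. That table was used for names, for the order of neighbouring genes and for X and Y chromosome membership, and no coordinates are printed because the build of the array is not given in the sources used here. Where a gene had several probe sets (999 genes), the one with the highest mean over the 4 arrays was used. Probe sets with a mean under the 25th percentile (4.71 on the log2 scale) were left out as dim, which left 14914 genes.

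Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, contrast knockout minus wild type), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Every log2 fold change given is knockout minus wild type. The lone wild type array has no spread of its own and is assumed to vary like the knockout arrays, which gives 2 residual degrees of freedom and 5.04 prior degrees of freedom. An exact permutation test of 1 array against 3 cannot give a p below 0.25. The number of arrays limits the precision of every value, and a p that misses the threshold does not show equal levels.

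Of 32 gene lists fixed from textbook knowledge before the data were examined, 30 were tested with camera (preset correlation 0.01), with camera on an estimated correlation and with fry beside it. Erythroid markers had 3 tested genes, under the minimum of 5, and sex-linked genes were read per array without a test. For each list the members past the threshold were also counted with p-values adjusted over the list alone. The NF-kB list was included because the study is known to deal with NF-kB in these hearts, so it is not independent evidence of its direction.

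Genes are named by a rule. It takes Fbxo32, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with all 3 knockout arrays on one side of the wild type array, filled up by smallest unadjusted p where fewer pass. It adds the 4 members of each called list with the largest change in the direction of the list, and always Nppa, Nppb, Myh7, Myh6, Acta1, Nfkbia, Il6, Ccl2, Icam1, Col1a1, Col3a1, Postn, Trim63 and Rcan1. Predicted genes, receptors of smell and genes known only by an accession are skipped (1 among the 20 of smallest p). Also computed were the genes in which any single array lies beyond the 3 others and at least 1.5-fold from their mean, and a permutation test (100000 random gene sets) of the mean absolute limma t of the 100 measured genes nearest to Fbxo32.

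The tests, samples, lists, naming rule and alternatives were chosen before the data were examined. Alternatives were renewed quantile normalization, centring, other filters, other probe set rules, other variance models, other set tests, other thresholds and leaving out each knockout array. Chosen after seeing the data were a covariate for the level of Xist (high or low), the comparison of wild type 1 with knockout 3 alone, neighbour sets of 50 and 200 genes, splits of the arrays into pairs, and the tubulin family. With the covariate, the genotype term rests on wild type 1 against knockout 3 and its spread on knockout 1 against knockout 2.

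Tested on simulated data with the same 1 array against 3 (20 runs, 14914 genes, 200 of them changed), the comparison recovered 1.9% of genes changed 1.5-fold, 8.5% of those changed 2-fold, 82.2% of those changed 3-fold and 94% of those changed 4-fold. On average 8.75 unchanged genes per run were called. The simulated noise was normal and independent between genes. On the real arrays genes moved together, with an estimated correlation of up to 0.951 within a list (cell cycle genes). The simulated shares therefore cannot be carried over to these arrays. There Hmox1 (5.99-fold) was called, but Sprr1a (12.5-fold) and Tnc (7.78-fold) were not. The SD over the knockout arrays was 0.14 for Hmox1, 1.52 for Sprr1a and 1.04 for Tnc.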

Results

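The deposited expression profiles covered 4 mouse hearts 1 week after aortic constriction, 1 wild type and 3 MAFbx knockout. MAFbx is a muscle F-box protein, the substrate-binding part of an SCF ubiquitin ligase. The comparison asks how its absence alters gene expression in the pressure-loaded heart. Array medians over the 14914 genes tested lay between 6.84 and 6.87 (log2). Across genes, which are not independent replicates, the Pearson correlation between arrays ran from 0.969 for wild type 1 with knockout 1 to 0.986 for knockout 1 with knockout 2, and wild type 1 with knockout 3 gave 0.984.

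Fbxo32 (probe set 10428796), the gene encoding MAFbx, read 7.54 on the wild type array and 5.65, 5.61 and 5.56 on the knockout arrays. The knockout mean was 5.61 ± 0.05 (SD, n = 3), 3.82-fold lower, with a log2 fold change of -1.93 (SE 0.17). With limma this narrowly missed the threshold over all genes (adjusted p = 0.0529), although the knockout arrays differed from each other far less than from the wild type array. The position of the probe set relative to the deleted part of the gene was not analysed here.

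The sex-linked transcripts, read per array without a test, divided the arrays differently from genotype. Xist, the RNA that coats the inactive X chromosome, read 4.13 in wild type 1 and 3.20 in knockout 3, against 9.18 in knockout 1 and 9.52 in knockout 2. The Y-linked gene Eif2s3y read 8.57 in wild type 1 and 8.49 in knockout 3, against 3.31 and 3.64 in knockouts 1 and 2. Uty gave 6.57 and 6.66 against 2.46 and 3.47, and Kdm5d 6.14 and 6.30 against 4.49 and 4.65. The labels do not state the sex of the animals. By these transcripts wild type 1 and knockout 3 read as male and knockouts 1 and 2 as female. The lone wild type heart shares its pattern with knockout 3 alone, so genotype is partly confounded with this difference. For each list called below, the median difference between knockout 3 and wild type 1, the Xist-low arrays, is therefore given beside the whole comparison.

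Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, was the 1 gene called among the 14914 tested. It fell 5.99-fold, from 9.98 to 7.40 ± 0.14 (SD, n = 3), a log2 fold change of -2.58 (SE 0.19, limma adjusted p = 0.0400). At an adjusted p under 0.1 there were 11 genes, all lower in the knockout hearts. At an unadjusted limma p under 0.05 there were 855 genes, 604 lower and 251 higher. Knockouts 1, 2 and 3, each set alone against the other arrays, gave 768, 490 and 486 genes at that level. Unchanged genes also pass an unadjusted threshold, so these counts alone do not show an effect of genotype. Without knockout 1, 2 or 3 the adjusted p of Hmox1 became 0.997, 0.995 and 0.334, and its log2 fold change -2.50, -2.63 and -2.62.

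After Hmox1, Fbxo32 and Ankrd2 had the smallest p, and neither they nor the genes below passed the threshold. Ankrd2, a stretch-responsive ankyrin repeat gene of striated muscle, read 8.07 in the wild type heart and 5.59 ± 0.24 (SD, n = 3) in the knockout hearts, a log2 fold change of -2.48 (SE 0.22, limma adjusted p = 0.0529). The log2 fold change was -1.87 for Clec4d, a C-type lectin of myeloid cells (adjusted p = 0.0535), and -1.72 for Saa3, an acute-phase serum amyloid (adjusted p = 0.0535). Arg1, arginase 1, stood at -1.80 with the same adjusted p, and its knockout values of 4.67, 4.61 and 4.85 lay around the filter level of 4.71. The chemokine genes Ccl9 and Ccl6 gave -1.74 and -1.50 (adjusted p = 0.0655 and 0.0784), and Ptgs2, encoding the inducible cyclooxygenase, gave -1.51 (adjusted p = 0.0979). The tubulin gene Tubb3 gave -1.42 (adjusted p = 0.0979).

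No gene higher in the knockout hearts passed the limma test. The 10 of smallest p were Islr (1.23), Ces2e (1.07), Htra3 (1.04), Itih5 (1.27), Fmo1 (0.84), Kcnip2 (0.92), Bcat2 (1.18), Car4 (0.84), Adamtsl2 (1.19) and Egf (0.78), given as log2 fold change, with adjusted p from 0.214 for Islr to 0.423 for Egf. Kcnip2 encodes a subunit of the cardiac transient outward potassium channel, and Bcat2 the mitochondrial aminotransferase of branched-chain amino acids.

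**Figure D1:**
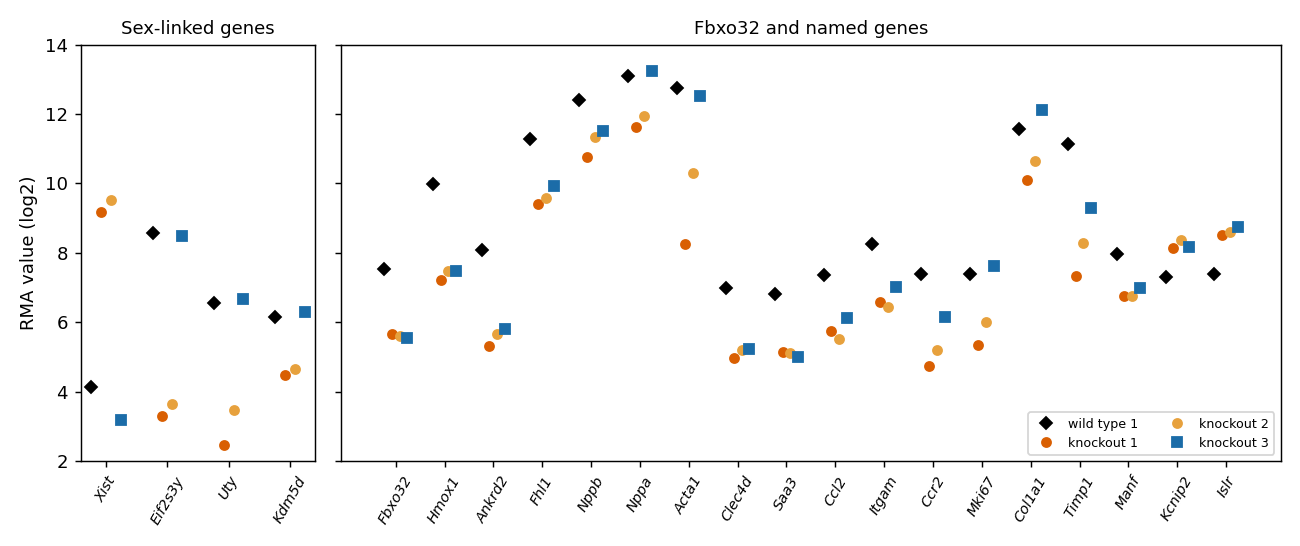
Log2 RMA value of sex-linked genes (left) and of Fbxo32 and named genes (right) on each of the 4 arrays, 1 symbol per array. Fbxo32, Hmox1 and Saa3 separate the wild type array (black) from all 3 knockout arrays, whereas for Mki67 and Col1a1 knockout 3 (blue) lies above the wild type array.

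The list of hypertrophy and fetal program genes was called lower in the knockout hearts. Across 24 members the median log2 fold change was -0.61, and 14 members had all 3 knockout arrays below the wild type array. For a single gene with interchangeable arrays chance gives 25%. Members of a list move together (estimated correlation 0.386 here), so such counts, here and below, describe these arrays and are not tests. The share over all genes tested is not given here. Camera gave an adjusted p = 1.65e-10 with the preset correlation and an adjusted p = 0.630 with an estimated correlation. Adjusted over the list alone, 8 members were lower, among them Ankrd2, Fhl1, Nppb and Rcan1, against 0 over all genes tested and 9 at an unadjusted limma p under 0.05. Fhl1, a LIM-domain gene of the sarcomere, stood at -1.63 (SE 0.24), Nppb, the gene for B-type natriuretic peptide, at -1.21 (SE 0.30), and Rcan1, a feedback inhibitor and target of calcineurin, at -0.88 (SE 0.24). Between knockout 3 and wild type 1 the median difference was -0.27, and without knockout 1 the list median was -0.39.

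For Acta1, Nppa and Myh7, knockout 3 read closer to wild type 1 than to knockouts 1 and 2. Acta1, skeletal alpha-actin, read 12.75 in wild type 1 and 12.52 in knockout 3, against 8.27 and 10.29 in knockouts 1 and 2 (adjusted p = 0.923). Nppa, atrial natriuretic peptide, read 13.09 and 13.23 against 11.62 and 11.94 (adjusted p = 0.932). Myh7, beta-myosin heavy chain, read 10.72 and 10.57 against 12.00 and 11.41 (adjusted p = 0.946), and Myh6, alpha-myosin heavy chain, lay between 13.12 and 13.28 on all 4 arrays. The calcineurin and NFAT list, with 20 members, was not called (median 0.08, adjusted p = 0.872).

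Macrophage markers gave the lowest median of the 30 lists. The 25 members had a median log2 fold change of -0.72, 19 lay below the wild type array on every knockout array, and camera gave an adjusted p = 6.83e-13, with an adjusted p = 0.630 with an estimated correlation. Adjusted over the list alone 8 members were lower (Ccr2, Cd68, Fcer1g, Fcgr1, Itgam, Lgals3, Mrc1 and Tyrobp), against 0 over all genes tested and 11 at an unadjusted limma p under 0.05. Ccr2, the receptor that draws monocytes into tissue, read 7.39 in the wild type heart and 5.37 ± 0.72 (SD, n = 3) in the knockout hearts. Itgam, the CD11b integrin subunit, gave -1.59, Cd68 -1.30 and the Fc receptor gene Fcgr1 -1.21. The difference between knockout 3 and wild type 1 was smaller, with a list median of -0.26, and there the endoplasmic reticulum stress list was lower (-0.385). Without knockout 2 the hypertrophy list was lower (-0.675 against -0.66), and without knockout 3 the extracellular matrix list was (-0.94 against -0.93).

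Among 38 tested NF-kB target genes, a list that is not independent evidence of its direction, 23 lay below and 6 above the wild type array on every knockout array. The median was -0.23 and camera called the list lower (adjusted p = 6.69e-08), with an adjusted p = 0.630 with an estimated correlation. Adjusted over the list alone, 7 were lower (Bcl3, Ccl2, Ccl7, Cxcl5, Lcn2, Ptgs2 and Saa3), against 0 over all genes tested and 11 at an unadjusted limma p under 0.05. Ccl2, the monocyte chemoattractant, stood at -1.55 (SE 0.25) and Cxcl5 at -1.34 (SE 0.18), whereas Nfkbia, the gene of the inhibitor IkB-alpha, was at 0.44 (SE 0.25; 0.275 without knockout 1) and Icam1 at -0.23 (SE 0.19). Il6 lay below the filter on dim genes, at 3.93 in the wild type heart and 2.69, 2.78 and 2.75 in the knockout hearts. In knockout 3 against wild type 1 the list median was -0.18.

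The endoplasmic reticulum stress, heat shock and ribosomal protein lists were called lower with the preset correlation of camera. Of 22 endoplasmic reticulum stress genes 15 lay below and 3 above the wild type array on every knockout array, with 7 lower adjusted over the list alone, 0 over all genes tested and 12 at an unadjusted limma p under 0.05 (camera adjusted p = 4.46e-08, and adjusted p = 0.630 with an estimated correlation). Manf, a secreted stress-induced factor of that compartment, stood at -1.14, Sdf2l1 at -0.97, and the disulfide isomerase genes Pdia6 and Pdia4 at -0.85 and -0.84. Among 16 heat shock genes 11 lay below and 1 above, with 1 lower adjusted over the list alone, Hspb1 (-1.46), and Hspa1a at -0.59 (camera adjusted p = 0.000473, and adjusted p = 0.630 with an estimated correlation). Of 41 cytosolic ribosomal protein genes 28 lay below the wild type array by small amounts, with a list median of -0.18 and Rpl30 at -0.63 (camera adjusted p = 0.000117, and adjusted p = 0.630 with an estimated correlation). In knockout 3 against wild type 1 the median difference was -0.39 for endoplasmic reticulum stress, -0.24 for heat shock and -0.17 for ribosomal proteins.

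Immediate early genes, induced fast by growth and stress signals, had a median of -0.16 over 28 members, 16 of which lay below and 3 above the wild type array on every knockout array. Gadd45g (-1.07) and Myc (from 8.03 to 7.03) were lower adjusted over the list alone, against 0 over all genes tested and 6 at an unadjusted limma p under 0.05, and Btg2 and Atf3 stood at -0.65 and -0.59. The list was called lower (camera adjusted p = 0.000240), with an adjusted p = 0.630 with an estimated correlation, and its median in knockout 3 against wild type 1 was -0.16. Without knockout 1 it was -0.26 and without knockout 2 it was -0.08.

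The cell cycle list was called lower, and 16 of its 30 members lay below and 0 above the wild type array on every knockout array, but Ccna2, Top2a and Mki67 read above the wild type level in knockout 3. Ccna2, cyclin A2, read 7.37 in wild type 1 and 7.44 in knockout 3, against 5.33 and 5.76. Top2a gave 6.92 and 7.08 against 4.89 and 5.45, and the proliferation marker Mki67 7.39 and 7.63 against 5.35 and 6.02. The mitotic kinase gene Plk1 gave 7.18 and 6.78 against 5.57 and 5.94. Over all members the median was -0.63, and -0.01 in knockout 3 against wild type 1 (camera adjusted p = 4.67e-10, and adjusted p = 0.630 with an estimated correlation), with 0 members past the limma threshold adjusted over the list alone and 4 at an unadjusted p under 0.05. With Xist as a covariate the adjusted p of the list was 0.845.

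The extracellular matrix list turned direction between the Xist-low and the Xist-high knockout arrays. Across 37 members, of which 7 lay below and 5 above the wild type array on every knockout array, the median was -0.41 (camera adjusted p = 0.0174, and adjusted p = 0.844 with an estimated correlation), but in knockout 3 against wild type 1 it was 0.53. Without knockout 1 it was 0.03 (adjusted p = 0.966), without knockout 2 it was -0.34 (adjusted p = 0.248) and without knockout 3 it was -0.94. With Xist as a covariate camera called the list higher at the preset correlation. That fit sets wild type 1 against knockout 3 alone and takes its spread from knockouts 1 and 2. The call therefore adds nothing to the 0.53 above. In the whole comparison the estimated correlation of the list was 0.870. Col1a1 read 11.58 in wild type 1, 10.10 and 10.66 in knockouts 1 and 2 and 12.11 in knockout 3, Col3a1 10.58, 9.03, 9.74 and 11.28, and Postn, a matrix protein of activated fibroblasts, 10.66, 8.85, 9.92 and 11.69. Adjusted over the list alone Tnc, Timp1 and Tgfb2 were lower, against 0 over all genes tested, and Tnc (-2.96, SE 0.66), Timp1 (-2.85, SE 0.62), Lox (-2.34, SE 0.85) and Thbs1 (-1.22, SE 0.41) lay below the wild type array on all 3 knockout arrays. In knockout 3 the difference was smaller, -1.87 for both Tnc and Timp1, -0.82 for Lox and -0.60 for Thbs1.

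The fatty acid oxidation, oxidative phosphorylation, FoxO and adult cardiomyocyte lists were called higher with the preset correlation of camera. Of 27 fatty acid oxidation genes 17 lay above the wild type array on every knockout array (median 0.30, camera adjusted p = 1.07e-07, and adjusted p = 0.630 with an estimated correlation), with Ucp3 at 1.15, Acot1 at 0.56, Ppara at 0.52 and Acads at 0.51. Without knockout 1, Acot1 and Acads were both at 0.31. Of 55 oxidative phosphorylation genes 39 lay above (median 0.19, camera adjusted p = 6.54e-07, and adjusted p = 0.630 with an estimated correlation), with Cox8b at 0.46, Cox7a2 at 0.41, Ndufs8 at 0.39 and Ndufa9 at 0.36, of which the last pair gave 0.215 and 0.22 without knockout 2. Among 29 FoxO and atrophy genes 18 lay above and 2 below (median 0.25, camera adjusted p = 1.06e-05, and adjusted p = 0.630 with an estimated correlation), with Sesn1 at 1.03, Ddit4 at 0.81, Bnip3 at 0.70 and Map1lc3a at 0.49. Trim63, the gene of the muscle ubiquitin ligase MuRF1, was at 0.25 (SE 0.23), and at 0.12 without knockout 2. Adult cardiomyocyte genes had a median of 0.16 over 21 members, of which 12 lay above and 1 below (camera adjusted p = 0.000326, and adjusted p = 0.630 with an estimated correlation), with Kcnip2 at 0.92, Kcnj2 at 0.66, Slc2a4 at 0.52 (0.335 without knockout 1) and Cacna1c at 0.52. With Xist as a covariate these 4 lists were no longer called (adjusted p = 0.388, 0.0704, 0.0839 and 0.109), and their medians, which equal those of knockout 3 against wild type 1, were 0.06, 0.06, 0.07 and 0.10. Without knockout 2 the FoxO median was 0.15.

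The lists of interferon-stimulated genes, endothelial markers and adipocyte markers were called higher with the preset correlation. For 23 interferon genes, of which 15 lay above the wild type array on every knockout array, the median was 0.21 (camera adjusted p = 5.17e-05, and adjusted p = 0.630 with an estimated correlation), with Iigp1 at 0.69, Rsad2 at 0.67, Gbp3 at 0.58 and Ifit3 at 0.43. For 19 endothelial markers, of which 8 lay above, it was 0.23 (camera adjusted p = 0.000658, and adjusted p = 0.630 with an estimated correlation), with Ramp2 at 0.48, Aqp1 at 0.46, Esam at 0.42 and Kdr at 0.37, and Aqp1 was at 0.235 without knockout 1. The medians in knockout 3 against wild type 1 were 0.32 for interferon genes and 0.44 for endothelial markers, and without knockout 3 the endothelial median was 0.12 (adjusted p = 0.0547). The 10 adipocyte markers, of which 4 lay above, had a median of 0.24 (camera adjusted p = 0.0170, and adjusted p = 0.630 with an estimated correlation), with Retn at 0.50, Car3 at 0.44, Cidec at 0.39 and Pparg at 0.29, and 0.03 in knockout 3 against wild type 1. Without knockout 2 it was 0.15 (adjusted p = 0.0857), with Car3 at 0.055 and Cidec at 0.16, and with Xist as a covariate its adjusted p was 0.561. Adjusted over the list alone, 0 members of these 3 lists, of the fatty acid oxidation, oxidative phosphorylation and FoxO lists, or of the ribosomal list passed the limma test, and Kcnip2 was the 1 adult cardiomyocyte gene that did.

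The other lists were not called. Camera gave an adjusted p = 0.167 for mesothelial and epicardial markers, 0.215 for antioxidant genes, of which Hmox1 is a member, 0.261 for circadian clock genes, and 0.286 for both fibroblast and skeletal muscle markers. It gave 0.421 for neutrophil markers, 0.431 for glycolysis, 0.698 for autophagy and lysosome genes, 0.716 for proteasome subunits, 0.732 for both SCF and muscle ubiquitin ligases and lymphocyte markers, 0.842 for atrial markers, and 0.872 for smooth muscle and pericyte markers. Median differences of knockout 3 from wild type 1 were 0.325 for fibroblast markers, 0.19 for skeletal muscle markers and -0.215 for proteasome subunits, against 0.19, 0.0033 and -0.07 in the whole comparison. Of the 30 lists tested, 16 were called with the preset correlation, 9 lower and 7 higher in the knockout hearts. No list was called with an estimated correlation or by fry. The adjusted p = 0.630 that most lists share is a tie produced by the adjustment. Unadjusted, camera with an estimated correlation gave p = 0.0397 for ribosomal proteins (correlation -0.0051) and p = 0.0447 for endoplasmic reticulum stress (correlation 0.046). It gave p = 0.296 for cell cycle genes (correlation 0.951) and p = 0.350 for oxidative phosphorylation (correlation 0.519).

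Setting any single array against the other 3 also produced list calls, 13 for knockout 1, 13 for knockout 2 and 11 for knockout 3, against 16 for the wild type array. The list calls therefore describe these arrays and do not separate genotype from differences between single hearts. The wild type array lay beyond the 3 others and at least 1.5-fold from their mean in 653 genes, 482 above and 171 below. Knockouts 1, 2 and 3 did so in 609, 323 and 347 genes.

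**Figure D2:**
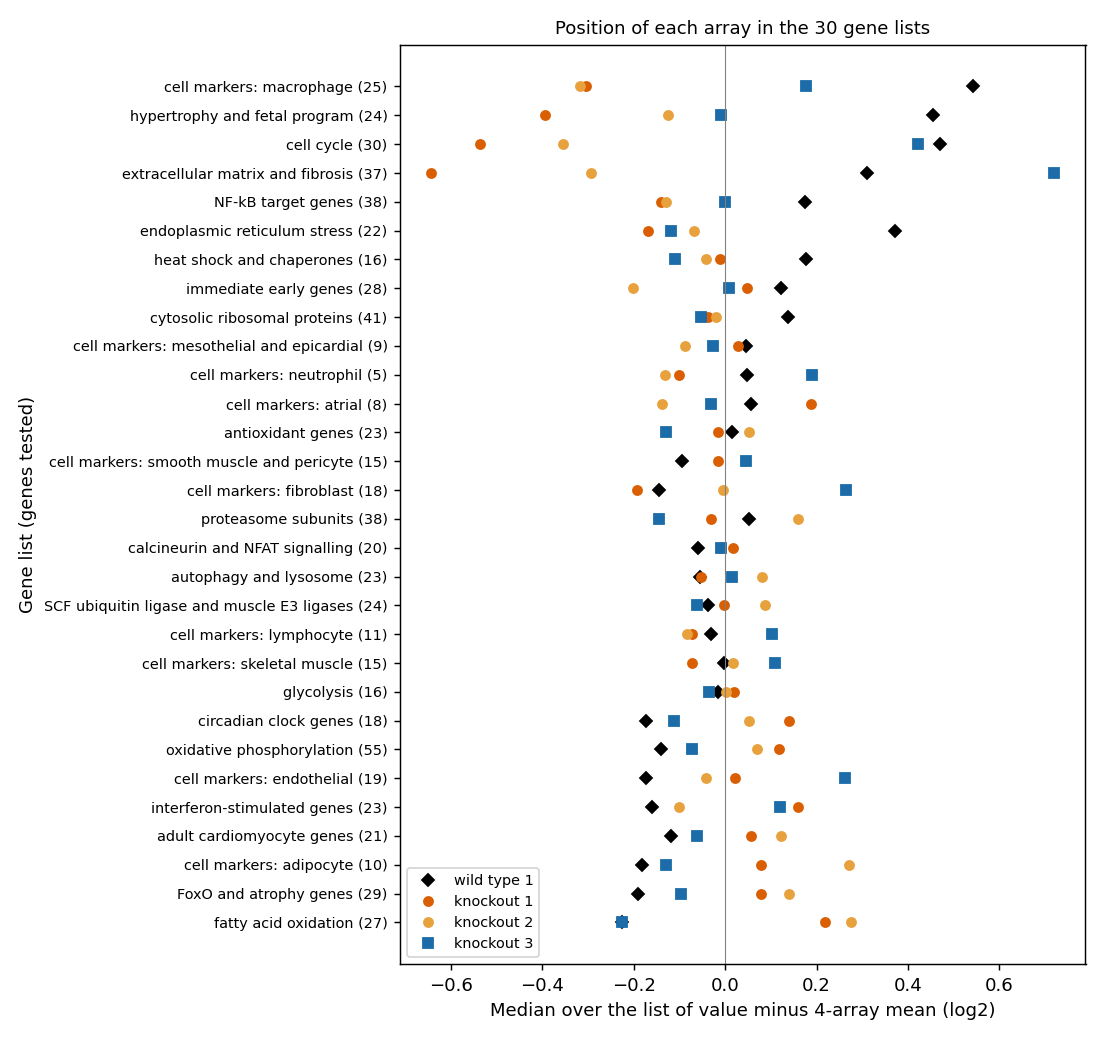
Median over each gene list of the members' log2 value minus their mean over the 4 arrays, 1 symbol per array, for the 30 lists tested (number of genes tested in parentheses). Wild type (black) lies apart from all 3 knockout arrays for endoplasmic reticulum stress. Knockout 3 (blue) lies between it and the other knockout arrays for macrophage markers, is near it for cell cycle genes and beyond it for extracellular matrix genes.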

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

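The Xist covariate and the comparison of wild type 1 with knockout 3 alone were chosen after seeing the data. No paired analysis was possible because the genotypes share only replicate number 1. The number of called genes, 1 with the settings above, was 0 after renewed quantile normalization, without the filter on dim genes, with the Xist covariate and in each fit without 1 knockout array, which all left Hmox1 lower. It was 2 with a filter at the 50th percentile, 7 with a variance trend, 11 with a robust trend, 9 without moderation and 11 at an adjusted p under 0.1. Fbxo32 kept a log2 fold change of -1.93 and passed with the trend (adjusted p = 0.0325) and the robust trend (adjusted p = 0.00973), over a range up to 0.997 without knockout 1. Against knockout 3 alone it was -1.98, and the stricter filter removed it, so that no value was had there. Leaving out arrays reduces the residual degrees of freedom to 1, and the lone wild type array is again assumed to vary like the others.

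No list was called with an estimated correlation (0 of 30) or by fry (0 of 30), where the medians stayed by construction at -0.72 for macrophage markers, -0.61 for the hypertrophy list and -0.23 for NF-kB targets. The other normalizations, filters, probe set rule, fits without 1 knockout array, rank-based camera and the Xist covariate gave 15 or 16 called lists. With the Xist covariate these included antioxidant genes, proteasome subunits and fibroblast, skeletal muscle and lymphocyte markers, not called without it. Those calls rest on wild type 1 against knockout 3 alone and use the preset correlation. Against knockout 3 alone the macrophage median was -0.26 and the hypertrophy median -0.27. The extracellular matrix median turned to 0.53 there and with the covariate, and over the fits without 1 knockout array it ran from -0.94 to 0.025. Postn ran from -1.275 to 0.145 over those fits. With the covariate and against knockout 3 alone, which have the same genotype difference by construction, signs turned for Nppa (0.14), Myh7 (-0.15), Col1a1 (0.53), Col3a1 (0.70), Postn (1.03), Ccna2 (0.07), Top2a (0.16), Mki67 (0.24), Aqp1 (-0.08), Car3 (-0.29) and Cidec (-0.06). The cause of these turns was not tested beyond what is given under other observations. The wild type array was set apart in 1773 genes at 1.3-fold, fewer than the 1843 of knockout 1, and in 145 at 2-fold, against 115. Windows of 5 and 20 Mb around Fbxo32 were not run, since positions on the build of the array were not used here.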

Other observations

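The tubulin genes, Sprr1a and Aldh1a2 were chosen after their values were seen. Of 13 tubulin genes tested 6 lay below it on all 3 knockout arrays and 0 above, with a median log2 fold change of -0.45, while Tubb1 and Tubb4a stood at 0.08 and 0.06. Tubb6 read 9.44 in the wild type heart and 7.87, 7.37 and 7.87 in the knockout hearts, Tubb2a 7.70 against a mean of 6.29 ± 0.28 (SD, n = 3), and Tubb2b 6.92 against 5.55, 5.62 and 5.97. The adjusted limma p was 0.190 for Tubb6 and 0.333 for both others. Camera on this family gave p = 1.29e-07, and p = 0.0353 with an estimated correlation, neither of which counts as a test since the family was picked from the values. Sprr1a, a stress-induced cornified envelope gene, had the lowest fold change of the genes tested (-3.65, adjusted p = 0.530), at 11.30 in the wild type heart and 6.22, 7.49 and 9.25 in the knockout hearts. Aldh1a2, a retinoic acid synthesis gene of the epicardium, stood at -2.75 (adjusted p = 0.296).

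Trim12a, also chosen after its values were seen, read 6.61 in wild type 1 and 6.55 in knockout 1 but 3.80 and 3.21 in knockouts 2 and 3. Among 6850 probe sets that carry several or no gene names limma called 0, with 269 at an unadjusted p under 0.05.

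Of the tests below, those on splits into 1 against 3, on the lists against the Xist pattern and on non-myocyte share were chosen after the results were seen, and so were the splits into pairs and the neighbour sets of 50 and 200 genes. The 1 called gene, Hmox1, was found in 1 of the 4 splits of 1 array against 3, the real one, and the highest of the other splits called 0. With 4 splits no share under 0.05 can be reached.

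The lists lower in the knockout hearts differed in how they followed the Xist pattern. If the sex-linked difference were the whole cause, wild type 1 and knockout 3 would share a list mean. They differed by 0.0077 for cell cycle genes (wild type minus knockout 3), against 0.25 between knockouts 1 and 2. For this list a sex-linked difference between the animals may account for the knockout mean being lower. For extracellular matrix genes they differed by -0.35, so the mean was not shared. Knockouts 1 and 2 differed by 0.47 in that list, so the comparison cannot decide. In both lists, variation between single hearts cannot be told apart from a sex-linked difference. For macrophage markers the difference was 0.41 against 0.04 between knockouts 1 and 2, which argues against it as the whole cause. Each of these values comes from only 1 pair of hearts, however. From the mean of knockouts 1 and 2 wild type 1 differed by more, 0.87, so a sex-linked difference as part of the cause stays open. For the hypertrophy list it was 0.43 against 0.31 and the question stays open, as does any difference in the strength of the constriction between animals, which was not tested. The remaining lower lists were not among those chosen for this test. The same values were 0.38 against 0.094 for endoplasmic reticulum stress, 0.34 against 0.022 for heat shock and 0.29 against 0.010 for NF-kB targets. They were 0.18 against 0.027 for ribosomal proteins and 0.19 against 0.24 for immediate early genes. In all but the immediate early genes the difference from knockout 3 was the larger value. Each value again rests on 1 pair of hearts, and some of those between knockouts 1 and 2 are very small. No conclusion on the cause is drawn for these lists.

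A larger share of all non-myocytes in the wild type sample would raise markers of every such type alike. Macrophage markers were higher there by 0.72 and endothelial markers lower by 0.21 in the mean. In list means, wild type minus knockout was 0.055 for fibroblast, 0.061 for smooth muscle and pericyte and -0.015 for lymphocyte markers. The list medians, as knockout minus wild type, were 0.19, 0.13 and 0.04. For fibroblast and for smooth muscle and pericyte markers the direction thus depends on the measure. The gap of 0.93 between macrophage and endothelial markers, the widest between these list means, exceeds the SD of 0.156 of the same gap over the 3 knockout arrays. These values argue against such a share as the whole cause, though that SD holds no spread between wild type hearts. A change in macrophages themselves, with genotype or with the single wild type heart, stays open as a hypothesis.

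Splitting the arrays into pairs gave 91 called genes for wild type 1 and knockout 3 against knockouts 1 and 2, and 0 for each of the other 2 splits into pairs (unadjusted 253 and 310 genes). Of the 91 genes 8 lie on the X or Y chromosome, while 12 of 30 cell cycle genes and 9 of 37 extracellular matrix genes are among them, so the split is not made up of X and Y genes alone.

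DNA flanking the targeted Fbxo32 allele could carry variants of the strain the allele was made in. The 100 measured genes nearest to Fbxo32 had a mean absolute limma t of 1.02 against 0.93 for random sets (permutation p = 0.153, and from 0.0723 for 50 to 0.255 for 200 neighbours), which leaves this open. Of these 100 genes 0 were called and 7 had an unadjusted limma p under 0.05. Over all 14914 genes tested 855 did, so the number 7 does not show a local cluster. The genes of this region chosen after their values were seen are Myc (7.03 against 8.03 in the wild type heart) and, as log2 fold changes, Sqle (-0.84), Cyrib (-0.89), Nudcd1 (-0.68) and Ccn3 (0.93). Myc is also among the immediate early genes above.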
